A study of Mus musculus with 6 samples.

How the data were processed

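RNA was measured by sequencing in 6 samples of mouse aortic smooth muscle cells, 3 treated with vehicle and 3 with the gamma-secretase inhibitor DAPT. Groups and replicate numbers were taken from the sample labels. The columns of the table carry the letters C and I with a number, and C was read as control and I as inhibitor, which the labels do not spell out. RNA was extracted with spin columns and libraries were made with a TruSeq RNA kit, per the labels' protocols. TopHat2 2.0.4, HTSeq 0.5.4p3, DESeq 1.16.0 and the mouse genome build mm9 are named, without their roles, in the submitters' processing notes. The annotation release, the filters and the use of strand in counting were not given in the sources used here.

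The deposited table held 37309 rows, 1 per Ensembl gene, of which 14349 had no read in any library. Per the file headers and the values, the authors deposited for each library a signal that equals the read count per gene divided by 1 size factor for that library. Whole reads could be recovered from these values: 100% of the values in each library were whole multiples of the value of 1 read, within 0.01 reads. This held for DAPT replicate 3 as well, but its size factor, 1.01, lies so near 1 that a rule on units applied here does not accept its values as recovered reads. Its total is given, and its reads were left out of the count tests. The authors also deposited a log2 ratio per gene, whose sign was that of DAPT over vehicle in 12210 of the 12213 genes with both group means above 50. The deposited p-value and adjusted p-value per gene were used only to set the authors' calls beside those made here. The test behind them was not given in the sources used here. Deposited RPKM values were not used here. The deposited length of a gene was used in 1 check of bias. The table gives a chromosome but no start or end for each gene, so no coordinates are printed.

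The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2 of the normalised count plus a pseudocount of 1. A gene was tested when its normalised count was at least 10 in at least 3 libraries, which left 14906 genes. The contrast was DAPT minus vehicle, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no covariate was fitted. Fold changes are differences between group means of log2(value + 1). The pseudocount makes the change of low genes smaller, but a very low value in a single library can make it larger. For Mfap4 the log2 change was -2.07, against a deposited log2 ratio of -1.90. The main design, 21 gene lists, the rule for named genes and the alternatives were set before the data were examined. The list test was camera with a preset correlation between genes of 0.01, adjusted over the 21 lists. It was repeated with an estimated correlation and with the fry rotation test, which asks whether a list's genes moved, on balance, one way and does not compare them with other genes as camera does. Members were also counted with p-values adjusted over the list alone. The lists covered Notch targets, Notch ligands, receptors and modifiers, gamma-secretase subunits, smooth muscle contractile genes, cartilage genes, sclerotome and skeletal progenitor factors, osteogenic genes, calcification inhibitors, fibrillar and elastic matrix, proteoglycans and matrix proteases, cell cycle genes, p53 targets, cholesterol synthesis, unfolded protein and amino acid stress, oxidative and xenobiotic response, inflammatory genes, interferon response, the response to TGF-beta and YAP, and markers of endothelial cells, of macrophages and leukocytes, and of adventitial fibroblasts.

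Named genes were 12 fixed genes, the 8 that rose most and the 8 that fell most among called genes with a mean of at least 50 and no overlap between groups, and up to 4 called members per list, taken from the 2 ends of the list, or the 2 most abundant members where none was called. Predicted genes without a symbol of their own were left out of the extremes, 2 among those that rose and 1 among those that fell. Some of the genes that the rule picks are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Where several rows shared a symbol, the row with the highest mean stood for the gene in lists.

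The procedure was tested on simulated counts drawn for the 2 groups from the real means and library sizes. The genes that were changed all had a mean of at least 50, so recovery of lower genes was not simulated. The spread of each gene was set by a trend with its level, so spread particular to single genes was not simulated either. In the simulated comparison of DAPT with vehicle, with 14772 genes tested, limma recovered 77.6% of genes changed 1.25-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold, and it called 1 of 14706 unchanged genes. The list test was run on 14800 genes of a separate simulated draw of DAPT against vehicle from the same means. It called the 1 list changed 1.3-fold and 0 of 20 unchanged lists by either camera or fry. Genes were drawn independently, so false list calls due to correlation between genes could not appear.

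Alternatives were a pseudocount of 0.5 or 5, no filter, a filter of 50, scaling by TMM factors, quantile normalisation, the replicate number as a block, robust empirical Bayes, 1 row per symbol, and each library left out in turn. The count tests of edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads of 5 libraries, without DAPT replicate 3, a restriction chosen after seeing the data. In the simulated comparison of DAPT with vehicle used for limma, with 14766 genes tested, edgeR on 5 libraries recovered 74.6% of the genes changed 1.25-fold. It recovered 98.5% of those changed 1.5-fold with 7 false calls, and DESeq2 recovered 53.7% and 85.1% with 0 false calls. A further 3 lists, a list of mitochondrial genes, a list of histone genes and the terms of the deposited functional annotation were tested after the data had been seen. For 1568 tested genes no such annotation was used here. GC content came from the transcripts of a later mouse reference, matched by Ensembl identifier, for 95.9% of the tested genes together with a length.

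Recovered totals ranged from 10702548 to 14503665 reads per library. A count of 0 in a library allows a true level of up to 3 reads, and such limits cover counting error only. Library pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.42 to 3.03, so no library was taken as a copy of another. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Genes with near-identical copies or overlapping and antisense partners may share reads, among them Gsta3, Ifit3, Ly6a, Bglap, Rtl1 and mt-Nd6, and their values are uncertain to that extent.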

Results

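Messenger RNA was profiled in vascular smooth muscle cells from the descending aorta of the Immorto mouse, a strain that carries a conditional simian virus large T antigen so that its cells can be kept growing in culture. The cells were kept for 3 days with DAPT at 50 uM or with DMSO as vehicle. DAPT inhibits gamma-secretase, the protease that releases the active intracellular part of Notch receptors. There were 3 libraries per group. Recovered totals were 13769352, 10702548 and 14503665 reads for vehicle replicates 1 to 3, and 13488512, 12159930 and 12967212 reads for DAPT replicates 1 to 3. Levels below are normalised read counts, given as mean ± SD with n = 3 per group. The comparison asked which transcripts depend on gamma-secretase in these cells, and the study's title places Sox9 and Jag1 at its centre.

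Under DAPT all 19 measured fibrillar and elastic matrix genes fell, as did the contractile genes Acta2 and Tagln and the Notch target Hes1, while Sox9 and the antioxidant gene Nqo1 rose. The matrix list had a camera adjusted p of 0.176 with an estimated correlation. Of 13 markers of adventitial fibroblasts 9 fell and 2 rose, and these markers include Mfap5, Dcn and Lum of the matrix lists. Of 10 mesothelial markers, listed only after the data had been seen, 8 fell. Of 14906 genes tested with limma, 2703 passed an adjusted p of 0.05, 1375 of them higher and 1328 lower under DAPT. Changes were mostly small: 12 genes rose and 59 fell by at least 2-fold. The median log2 change over all tested genes was 0.0009. In 2605 of the called genes the 3 DAPT values did not overlap the 3 vehicle values, and 33.3% of all tested genes showed no overlap, where chance gives 10%. The authors' deposited table gave 1421 genes an adjusted p below 0.05, 714 higher and 707 lower, and all 1421 were also called here. The first principal component held 42.3% of the variance and separated the groups. With DESeq2 on 5 libraries the count was 976, and without vehicle replicate 3 the genes at least 2-fold higher numbered 22.

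Among the genes that rose most was Opcml, a cell adhesion molecule of the immunoglobulin family, at 92.6 ± 11.8 in vehicle and 225 ± 6.84 under DAPT, 2.43-fold higher (limma adjusted p = 1.55e-09). Plin4, a lipid droplet coat protein, rose 2.26-fold, from 114 ± 7.69 to 258 ± 15.8. Tgfbi, a secreted matrix protein induced by TGF-beta, rose 1.91-fold, the transcription factor Spib 1.87-fold, the imprinted zinc finger gene Plagl1 1.84-fold, the glutathione transferase Gsta3 1.76-fold, and Itgb2, an integrin subunit known from leukocytes, 1.74-fold. The mitochondrial gene mt-Nd6 rose 1.75-fold, from 5002 ± 1280 to 8575 ± 674, a call that was lost with robust empirical Bayes (adjusted p = 0.0771). Kif26b, a kinesin family member, fell from 167 ± 14.8 to 41.1 ± 4.42, 3.99-fold lower (limma adjusted p = 3.42e-11). Wnt2b, a Wnt ligand, was 3.44-fold lower, Lrrn4 2.80-fold, the imprinted gene Rtl1 2.50-fold, Cdh3 (P-cadherin) 2.42-fold, and the Wnt modulator Sfrp4 2.25-fold. Lox, which cross-links collagen and elastin, and Fmod, a collagen-binding proteoglycan, were also among the 8 that fell most. The share of reads in mitochondrial genes was 2.05% ± 0.143 in vehicle and 2.52% ± 0.25 under DAPT, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow.

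Hes1, a direct transcriptional target of Notch on chromosome 16, fell from 326 ± 5.88 to 211 ± 11.5, 1.54-fold lower (log2 change -0.62, SE 0.0726, limma adjusted p = 6.35e-07). Jag1, a Notch ligand on chromosome 2, was at 1223 ± 30.5 and 1112 ± 23.6 (log2 change -0.14, SE 0.0412, limma adjusted p = 0.0207). Notch3 was at 1868 ± 9.68 and 1861 ± 43.5 (adjusted p = 0.938) and the feedback inhibitor Nrarp at 44.6 ± 8.57 and 44.5 ± 2.83 (adjusted p = 0.972), neither past the threshold. Hey1, Hey2, Heyl and Hes5 lay below the filter: Hey2 was at 13.6 ± 5.86 and 7.66 ± 1.76, Hey1 at 1.93 ± 0.822 and 0.316 ± 0.547, and Heyl at 0.295 ± 0.511 and 0.701 ± 1.21. Hes5, a member chosen after its value was seen, had 0 reads in all 6 libraries. Without a filter, Hey2 had a limma adjusted p of 0.317 and Hey1 of 0.118. Of the 11 Notch targets listed, 5 were measured, 0 rose, 2 fell and 3 did not pass, with the same 2 when adjusted over the list alone. The list's median log2 change was -0.14, with a camera adjusted p of 0.0790. The Jag1 call was lost without vehicle replicate 2 (adjusted p = 0.103), without DAPT replicate 2 (0.101), without DAPT replicate 3 (0.0660) and in edgeR on 5 libraries (0.0643). Jag1 was also not among the genes with an adjusted p below 0.05 in the authors' deposited table. With camera the Notch target list passed the threshold with a filter of 50 (0.0418), without vehicle replicate 1 (0.0455) and without DAPT replicate 1 (0.0231), and fry, which does not compare the list with other genes, gave 0.00763.

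Among 18 measured Notch ligands, receptors and modifiers, 2 rose, 4 fell and 12 did not pass, with the same counts when adjusted over the list alone. The ligand Dll1 fell from 20.4 ± 3.18 to 8.62 ± 0.261 and the non-canonical ligand Dlk1 from 1119 ± 110 to 586 ± 4.87. Adam17, a protease that can cleave Notch receptors at the cell surface, rose from 1711 ± 26.7 to 1959 ± 13.8. The list as a whole did not pass (camera adjusted p = 0.480), with a median log2 change of -0.01. Of 7 gamma-secretase subunits 1, Ncstn, was called lower, and also when adjusted over the list alone, at 2757 ± 105 and 2558 ± 41.2 (log2 change -0.11, limma adjusted p = 0.0404). The call of Ncstn was lost without vehicle replicate 1, without any 1 of the DAPT replicates, without a filter and in edgeR on 5 libraries. The subunit list had a camera adjusted p of 0.819, with a median log2 change of -0.02 and a mean of 0.00754, so that the direction of the test and the median differed in sign.

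Sox9, the transcription factor that directs cartilage formation (chromosome 11), rose from 599 ± 39.6 to 843 ± 32.2, 1.41-fold higher (log2 change 0.49, SE 0.0532, limma adjusted p = 1.97e-07). Of 27 cartilage genes listed, 9 were measured, of which 1 rose, 3 fell and 5 did not pass, with the same counts when adjusted over the list alone. The 1 that rose was Sox9 itself. Fmod fell from 794 ± 73.7 to 336 ± 16.6, Col11a1, a minor cartilage collagen, from 49.8 ± 6.19 to 23.3 ± 5.36, and Prg4, the lubricant proteoglycan of joints, from 1117 ± 62.3 to 716 ± 28.0. Acan, the main cartilage proteoglycan, had 0 reads in vehicle and 2 reads over the DAPT libraries, under the limit of 3 reads. Col2a1, the main cartilage collagen, lay below the filter at 9.71 ± 2.19 and 3.99 ± 0.210, with a limma adjusted p of 0.0874 when no filter was applied. The cartilage list had a median log2 change of -0.08 and a camera adjusted p of 0.214, while fry, which does not compare the list with other genes, gave 0.00136 in the lower direction.

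None of 8 measured sclerotome and skeletal progenitor factors passed, also when adjusted over the list alone. The most abundant of them were Prrx1, at 6356 ± 175 and 6622 ± 114, and Twist1, at 603 ± 18.6 and 650 ± 23.3, and the list had a camera adjusted p of 0.314 with a median log2 change of 0.08. Of 8 osteogenic genes 1 rose, 1 fell and 6 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.480). Bglap, which encodes osteocalcin and has near-identical copies that may share its reads, rose from 28.6 ± 7.03 to 49.0 ± 1.6, and Bmp4, a bone morphogenetic protein, fell from 321 ± 26.1 to 192 ± 9.91. Among 8 measured calcification inhibitors, 5 fell, 1 rose and 2 did not pass, with the same counts when adjusted over the list alone, and the median log2 change was -0.41 (camera adjusted p = 0.00753, and adjusted p = 0.176 with an estimated correlation). Tnfrsf11b, which encodes osteoprotegerin, fell from 74.1 ± 13.2 to 43.1 ± 7.87, and Ank, a pyrophosphate transporter, rose from 222 ± 14.3 to 276 ± 7.49. Mgp, matrix Gla protein, a member chosen after its value was seen, fell from 3975 ± 193 to 2852 ± 70.2. Fbn1, chosen in the same way, encodes fibrillin-1, itself a matrix protein, and fell from 9782 ± 1291 to 7165 ± 266. Of the 5 that fell, Nt5e was no longer called without any 1 of the 6 libraries, with a pseudocount of 5, without a filter, with quantile normalisation, with the replicate block, with robust empirical Bayes or in edgeR on 5 libraries. Enpp1 was no longer called without vehicle replicate 1, without DAPT replicate 2 or 3, or in edgeR on 5 libraries.

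Among contractile genes Acta2, smooth muscle alpha-actin, fell from 520 ± 50.8 to 252 ± 26.3, 2.07-fold lower (log2 change -1.05, SE 0.0782, limma adjusted p = 4.23e-10), and Tagln, the actin-binding protein transgelin, fell from 925 ± 60.6 to 495 ± 36.1. Sncg, gamma-synuclein, rose from 201 ± 29.5 to 294 ± 5.52. Myh11, smooth muscle myosin heavy chain, was low in both groups, at 49.2 ± 4.28 and 47.1 ± 3.99, and did not pass (limma adjusted p = 0.845). Other listed genes, chosen after their values were seen, were low or absent in both groups. Cnn1 was at 14.7 ± 5.97 and 7.53 ± 5.93 (limma adjusted p = 0.0973). Myocd lay below the filter at 0.400 ± 0.693 and 0.330 ± 0.572, and Kcnmb1 and Pln were at 0. Of 18 measured members 1 rose, 8 fell and 9 did not pass, and 1 rose and 9 fell when adjusted over the list alone. The median log2 change was -0.21 (camera adjusted p = 0.00409, and adjusted p = 0.365 with an estimated correlation).

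**Figure D1:**
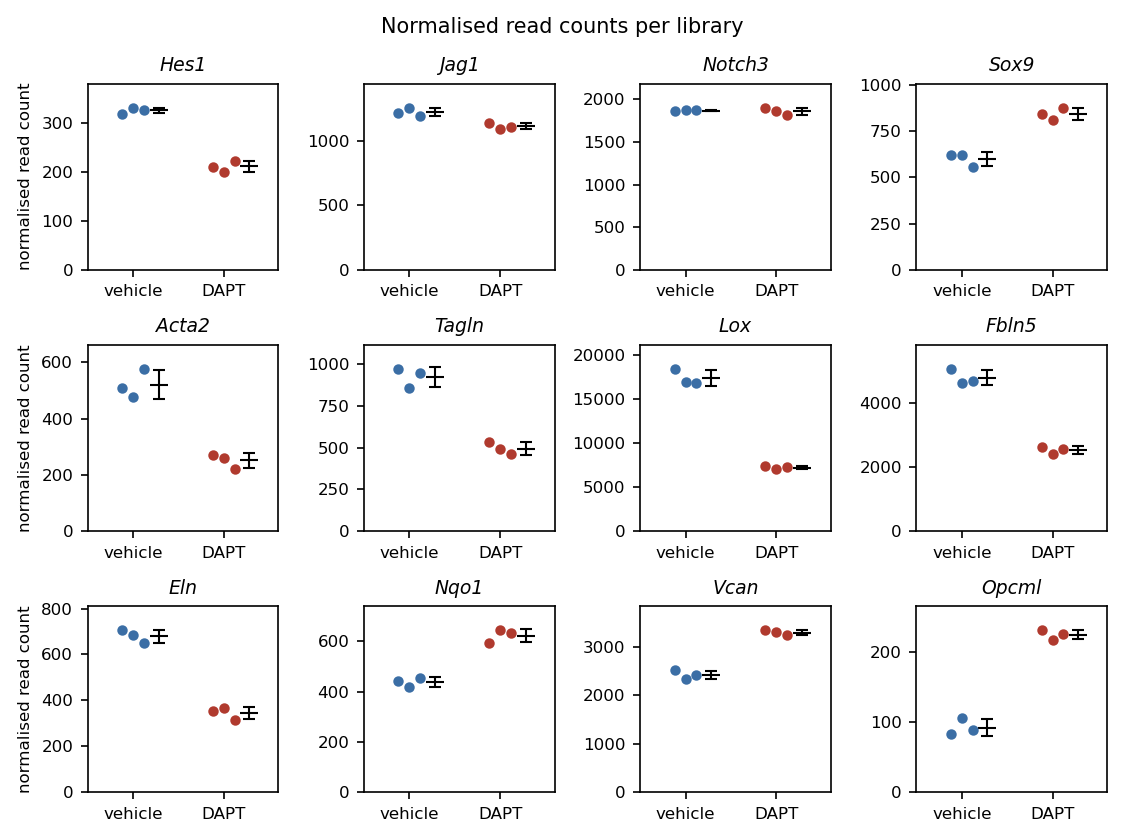
Normalised read counts (vertical axes, from 0) of 12 genes in each of 3 vehicle libraries (blue points) and 3 DAPT libraries (red points), with black bars for the mean ± SD of each group. Hes1, Acta2, Tagln, Lox, Fbln5 and Eln lie lower under DAPT in all 3 libraries, Sox9, Nqo1, Vcan and Opcml lie higher, and the Notch3 values of the groups overlap.

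Extracellular matrix genes fell together. All 19 measured members of the fibrillar and elastic matrix list fell, also when adjusted over the list alone, with a median log2 change of -0.49 (camera adjusted p = 1.59e-15, and adjusted p = 0.176 with an estimated correlation). Lox fell from 17372 ± 903 to 7224 ± 199, 2.40-fold lower (limma adjusted p = 1.55e-17). Mfap4, a microfibril-associated protein, fell from 19.3 ± 5.95 to 5.13 ± 5.49, near the filter, and its log2 change of -2.07 became -2.78 without DAPT replicate 1 and -1.48 without DAPT replicate 2. The smallest changes were those of Emilin1, at 5117 ± 88.2 and 4409 ± 82.5, and Loxl2, at 5745 ± 347 and 5046 ± 193. Among members chosen after their values were seen, Eln (elastin) fell from 680 ± 27.6 to 346 ± 27.8, Fbln5, which takes part in elastic fibre assembly, from 4788 ± 230 to 2530 ± 116, and the collagen gene Col3a1 from 24247 ± 2369 to 14723 ± 194. Of 18 proteoglycans and matrix proteases 4 rose, 11 fell and 3 did not pass, with the same counts when adjusted over the list alone (median log2 change -0.31, camera adjusted p = 0.00735, and adjusted p = 0.365 with an estimated correlation). Timp3, an inhibitor of matrix proteases, fell from 23845 ± 728 to 12443 ± 270 and Aspn, a small leucine-rich proteoglycan, from 41.8 ± 13.3 to 16.8 ± 6.16. Vcan (versican) rose from 2416 ± 86.8 to 3288 ± 49.3 and the hyaluronan synthase Has2 from 104 ± 11.8 to 151 ± 7.81.

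Markers of adventitial fibroblasts, cells that lie outside the muscle layer of the aorta, moved with the matrix genes. Of 13 markers 9 fell, 2 rose and 2 did not pass, and 9 fell and 3 rose when adjusted over the list alone, with a median log2 change of -0.29 (camera adjusted p = 0.00409, and adjusted p = 0.535 with an estimated correlation). Igf1 fell from 2031 ± 284 to 922 ± 28.0 and Lum from 96.8 ± 28.9 to 51.3 ± 4.47, while Ly6a rose from 9435 ± 244 to 10868 ± 454 and Gsn from 15907 ± 370 to 17473 ± 364. Of these markers Mfap5, Dcn and Lum are also members of the matrix lists. A list of mesothelial markers, made after the data had been seen, moved the same way, with 8 of 10 measured markers lower and a median log2 change of -0.51.

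Genes of the TGF-beta and YAP list, which holds TGF-beta ligand genes as well as responding genes, mostly fell. Of 16 members 11 fell, 2 rose and 3 did not pass, and 12 fell and 2 rose when adjusted over the list alone, with a median log2 change of -0.38 (camera adjusted p = 5.41e-05, and adjusted p = 0.176 with an estimated correlation). Ctgf, connective tissue growth factor, fell from 735 ± 130 to 456 ± 35.6. Tgfbi and Ankrd1 went the other way, Tgfbi from 91.4 ± 13.4 to 174 ± 2.86 and Ankrd1 from 187 ± 18.2 to 228 ± 13.8. The call of Ankrd1 was lost without vehicle replicate 2 and without DAPT replicate 1 or 2.

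Genes of antioxidant and detoxifying enzymes were mostly higher. Of 12 measured members of the oxidative and xenobiotic response list 7 rose, 2 fell and 3 did not pass, and 8 rose and 2 fell when adjusted over the list alone, with a median log2 change of 0.25 (camera adjusted p = 0.00095, and adjusted p = 0.176 with an estimated correlation). The quinone reductase Nqo1 rose from 438 ± 19.6 to 622 ± 26.5 and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, from 1692 ± 71.7 to 2389 ± 29.9. Cyp1b1, a target of the aryl hydrocarbon receptor, fell from 12140 ± 272 to 10709 ± 262. In the unfolded protein and amino acid stress list of 17 genes 5 rose, 2 fell and 10 did not pass, and 6 rose and 4 fell when adjusted over the list alone. Asns, asparagine synthetase, rose from 593 ± 20.8 to 783 ± 34.6 and Ddit3, a stress-induced transcription factor, from 1063 ± 102 to 1376 ± 58.1, while the list did not pass (median log2 change 0.03, camera adjusted p = 0.480).

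Cell cycle and p53 genes moved little. Of 26 cell cycle genes 4 rose, 0 fell and 22 did not pass, with the same counts when adjusted over the list alone, and the median log2 change was 0.06 (camera adjusted p = 0.0107, and adjusted p = 0.176 with an estimated correlation). Ccne2, cyclin E2, rose from 677 ± 20.9 to 823 ± 14.1. Without vehicle replicate 3 the list had a camera adjusted p of 0.0504. Of 15 p53 targets 3 rose, 0 fell and 12 did not pass, with the same counts when adjusted over the list alone (median log2 change 0.03, camera adjusted p = 0.278). Trp53inp1 rose from 9414 ± 327 to 10995 ± 235 and Ccng1 from 18221 ± 719 to 20385 ± 427. Of 21 measured cholesterol synthesis genes 1 rose, 5 fell and 15 did not pass, with the same counts when adjusted over the list alone. Insig1, which holds back sterol synthesis, rose from 1583 ± 140 to 1917 ± 63.2, and Srebf2, a regulator of the pathway, fell from 3376 ± 74.8 to 3037 ± 52.9. The cholesterol list had a median log2 change of -0.08 (camera adjusted p = 0.0372, and adjusted p = 0.627 with an estimated correlation), and its call was also lost without vehicle replicate 3 (0.367) and without DAPT replicate 3 (0.12), and fry gave 0.214.

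Inflammatory genes were more often lower, and interferon response genes higher. Of 14 inflammatory genes 3 rose, 6 fell and 5 did not pass, and 3 rose and 7 fell when adjusted over the list alone (median log2 change -0.16, camera adjusted p = 0.0159, and adjusted p = 0.365 with an estimated correlation). The chemokine Cxcl12 fell from 29416 ± 993 to 16983 ± 290 and Ptgs2, cyclooxygenase, from 324 ± 15.8 to 217 ± 15.1, while the chemokine Ccl2 rose from 1353 ± 22.2 to 1578 ± 83.2. Of 20 interferon response genes 9 rose, 0 fell and 11 did not pass, and 12 rose and 0 fell when adjusted over the list alone (median log2 change 0.09, camera adjusted p = 0.00095, and adjusted p = 0.365 with an estimated correlation). The antiviral gene Rsad2 rose from 3551 ± 169 to 4388 ± 87.8 and Ifit2 from 2875 ± 6.0 to 3442 ± 49.7. Markers of blood and vessel-lining cells were few. None of 6 measured endothelial markers passed, also when adjusted over the list alone, Kdr being the most abundant at 541 ± 18.1 and 529 ± 14.2 (camera adjusted p = 0.932, with a median log2 change of 0.03 and a mean of -0.03, which differ in sign). Of 4 measured macrophage and leukocyte markers 1 rose, also when adjusted over the list alone, and 3 did not pass (median log2 change 0.06, camera adjusted p = 0.480). The 1 that rose was Cd68, from 178 ± 12.0 to 218 ± 2.53, a call lost without vehicle replicate 1 and without DAPT replicate 2. In all, 11 of the 21 lists passed with camera, 8 lower and 3 higher, and 0 of the 21 with an estimated correlation.

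**Figure D2:**
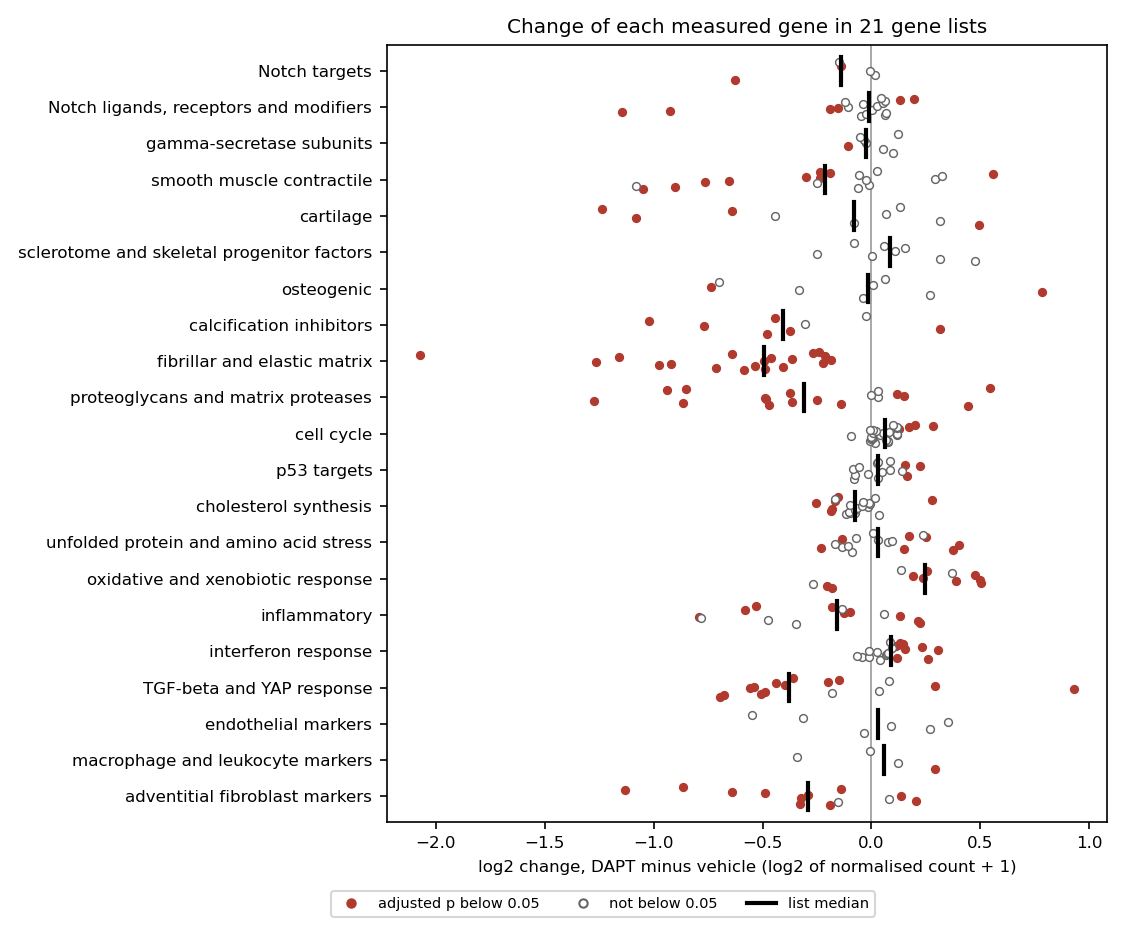
Log2 change (horizontal axis, DAPT minus vehicle) of each measured gene in the 21 lists (rows); filled red points passed an adjusted p of 0.05 in limma, open points did not, and black bars mark list medians. All 19 fibrillar and elastic matrix genes lie below 0, and the oxidative and xenobiotic response list has the highest median, 0.25.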

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

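The count tests on the recovered reads of 5 libraries and the lists made later were chosen after the data had been seen. Calls numbered 1864 (without DAPT replicate 2) to 2752 (robust empirical Bayes) over the limma settings, 1938 in edgeR and 976 in DESeq2, against 2703. DESeq2 called 443 genes higher and 533 lower, with 4 and 39 at 2-fold, where limma had 12 and 59. On the same 5 libraries limma called 1954, and in the simulation of DAPT against vehicle on them DESeq2 recovered 53.7% of the genes with the smallest simulated change and edgeR 74.6%. The genes at least 2-fold higher numbered 6 with a pseudocount of 5, 44 without a filter and 2 with a filter of 50, and 9 to 22 with 1 library left out, 22 without vehicle replicate 3. Those at least 2-fold lower numbered 34, 100 and 25 under the same 3 settings, which by construction shrink, add or remove low genes. The Notch target list passed with a filter of 50 (0.0418), and ran from 0.0231 to 0.195 with 1 library left out. Fry, which does not compare a list with other genes, gave 0.00763 for the Notch targets and 0.00136 for the cartilage list. With an estimated correlation the adjusted p was 0.365 for the contractile, proteoglycan, inflammatory and interferon lists, 0.176 for the calcification inhibitor, fibrillar matrix, cell cycle, oxidative and TGF-beta and YAP lists, 0.627 for cholesterol synthesis and 0.535 for adventitial markers. With 1 library left out the cell cycle list ran from 0.00390 to 0.0504 and cholesterol synthesis from 0.00636 to 0.367, and fry gave 0.214 for the latter. Lists that had not passed changed direction without passing: gamma-secretase subunits (0.578 to 0.972 with 1 library left out), endothelial markers (0.656 without a filter, 0.580 to 0.891 with 1 library left out) and leukocyte markers (0.656 without a filter). So did 3 genes that had not passed: Notch3, from -0.0217 to 0.0118 with 1 library left out and 0.00979 in edgeR, Nrarp, from -0.13 to 0.14, and Myh11, from -0.14 to 0.00614 and 0.00958 in edgeR. The causes were not tested.

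The labels number the libraries 1 to 3 in each group, but the numbers did not pair them: deviations from the group means correlated across genes at 0.0267, -0.0175 and 0.00990 in the same-numbered pairs, and not every library correlated best with its own number. With the replicate number as a block 2732 genes passed, 1396 higher and 1336 lower, 2639 of them shared with the 2703, and no list call changed. Among named genes the block ended 1 call, that of Nt5e. Hey1 (6 reads in vehicle and 1 under DAPT) and Acan (0 and 2) rest on so few reads that depth limits what can be said of them.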

Other observations

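The mesothelial, imprinted and lysosomal lists, the mitochondrial and histone lists, the split of mitochondrial genes by tail, the annotation terms and the tests of cell shares were chosen only after the data had been seen. Of 32 measured lysosomal genes 22 rose, 0 fell and 10 did not pass, with a median log2 change of 0.19 (camera adjusted over 5 added lists, p = 1.74e-10, and adjusted p = 0.223 with an estimated correlation). Gpnmb, a lysosomal membrane glycoprotein, rose from 3557 ± 362 to 5971 ± 188, the alpha-galactosidase Gla from 676 ± 18.97 to 870 ± 53.4, and Hexa, a hexosaminidase subunit, from 2192 ± 47.4 to 2793 ± 115. Of 1079 annotation terms 31 passed with camera, 10 higher and 21 lower, and 0 with an estimated correlation. The term for lysosome held 121 genes, of which 30 rose and 6 fell, with a median log2 change of 0.07 (camera adjusted p = 0.00551), the term for lysosomal membrane 79 genes, of which 24 rose and 4 fell (camera adjusted p = 0.00226), and the term for basement membrane 46 genes, of which 2 rose and 30 fell (camera adjusted p = 9.91e-10).

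Imprinted genes that are expressed together in growing tissues moved in both directions. Of 17 measured genes 2 rose and 7 fell, with a median log2 change of -0.11 (camera adjusted p = 0.0318, and adjusted p = 0.349 with an estimated correlation). The list holds Rtl1, Plagl1 and Dlk1, named above for their changes, so its test is not independent of them. The growth factor gene Igf2 fell from 1086 ± 48.9 to 575 ± 35.8 and the noncoding RNA H19 from 7595 ± 1028 to 4836 ± 177, while Plagl1 rose from 74.3 ± 9.54 to 137 ± 5.86.

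The lower level of matrix genes may reflect a response of the cells to DAPT or a technical shift. The median log2 change of the 19 genes stayed at -0.490268 under the scaling nearer 0 of TMM and quantile normalisation. The fall thus did not depend on the choice among these scalings. They differed little, with a median over all tested genes of 0.00436 under TMM and 0.00725 under quantile normalisation. Both set whole libraries level, so a shift of most genes together could not be seen. After a trend with length, GC content and abundance was removed from all tested genes, the median of the 19 genes was -0.455165, from -0.493735 before, which argues against that trend as the whole cause. Equal falls would be predicted for a lower share of adventitial fibroblast-like cells only if those cells alone made the markers and the matrix genes. Whether they did was not known. With Mfap5, Dcn, Lum and the collagen gene Col14a1 set aside, 8 of the other 9 markers had a 95% interval above the matrix median. These values cannot decide on cell share, which stays open. An effect of gamma-secretase inhibition, the difference that the design names, also stays open.

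Markers of mesothelium, the lining of body cavities, were plainly expressed and 8 of 10 fell (median log2 change -0.51, camera adjusted p = 1.74e-10, and adjusted p = 0.0136 with an estimated correlation), among them Upk3b, from 1350 ± 51.4 to 671 ± 40.5, Bnc1, from 2124 ± 68.2 to 1478 ± 35.8, and Msln, from 303 ± 31.7 to 178 ± 4.18. The median was -0.509886 under the scaling nearer 0, so the fall did not depend on the choice among these scalings, which differed little. A lower share of mesothelial-like cells could lower them alike, and 1 of the 10 had a 95% interval above the list's median. The intervals of Lrrn4 (-1.63 to -1.33), Upk3b (-1.11 to -0.908) and Msln (-0.925 to -0.585) lay below it. Their changes were nevertheless unequal beyond the errors that limma gave (heterogeneity Q test against the chi-square distribution, n = 10 markers taken as independent, p = 4.76e-56). A change in cell share and a change of expression within cells cannot be told apart here, because no sample holds 1 cell type known to be pure and Ezr and Krt19 are also made by other cells, and Lrrn4 had been seen to fall before the list was made.

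Mitochondrial genes were higher under DAPT, 14 of 22 having risen and 0 fallen, with a median log2 change of 0.32 (camera adjusted p = 1.56e-07, and adjusted p = 0.237 with an estimated correlation). Carry-over of RNA without a poly(A) tail could also raise histone genes whose transcripts lack one. The median of 13 histone genes was -0.216723, with a standard error of 0.0856, 0 having risen and 2 fallen (camera adjusted p = 0.0402, and adjusted p = 0.223 with an estimated correlation). Which of their transcripts lack a tail was not checked, and the list holds a pseudogene, Hist2h3c2-ps. These genes therefore cannot decide whether carry-over took part. Within the mitochondrial genes, 3 of the 8 whose transcripts lack a tail (mt-Nd6 and transfer RNA genes) rose, with a median of 0.40. Of the 2 ribosomal RNA genes 2 rose, with a median of 0.55. Of the 12 mRNAs that carry a tail 9 rose, with a median of 0.28. The differences between these kinds were not tested, so carry-over, also if limited to mitochondrial RNA, is not settled by these values. The mitochondrial median was 0.322669 under the scaling nearer 0, so the rise did not depend on the choice among these scalings, which differed little. RNA quality was not tested, and a response of mitochondrial transcription to DAPT stays a hypothesis.

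The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2703 called genes and the highest of the others 0, so that 1 of 10 splits gave as many; for lists it gave 11 against a highest of 4, again 1 of 10.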
